A study of Drosophila melanogaster with 7 samples.

How the data were processed

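The samples were Drosophila embryonic cells collected at 25 degrees, cross-linked with 1% formaldehyde for 10 min and sorted by GFP, per the labels' protocols. Libraries were made from 10 ng of input DNA, or less IP DNA, with a size selection of 200 bp and 18 cycles of PCR, and sequenced on an Illumina GAIIx instrument, per the labels. The FLAG antibody was used for Ada2b and for the untagged control, and antibody 4H8 for Pol II. Groups were taken from the sample titles.

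Each deposited file is a list of aligned reads in BED format, in genome build dm3 per the submitters' processing notes, and the authors gave 1 row per read with its position and strand (an other kind of unit, positions with no scaling). All rows were 1 base long, and the score that the authors deposited in each row was 0 throughout and was not used. The aligner, read filters and the handling of repeated reads are not given in the sources used here. Per the labels, the 2 Ada2b files and the Pol II file each pool 2 replicates. In these 3 files, repeated rows per position and strand were present on 2L, 2R, 3L, 3R and 4 (3.59, 3.96 and 1.31 rows per distinct position) and were absent or limited on X (1.0, 1.40 and 1.0), while the untagged IP and the inputs held 1 row per position on every arm. Each row was taken as the 5′ end of a read, since rows of the minus strand lay downstream of those of the plus strand.

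Before the data were examined, the following rule was set. Reads on the 6 arms were reduced to 1 per position and strand, moved 100 bases along their strand and counted in windows of 1000 bases. The IP/input ratio was scaled to the reads of each library on these arms, and windows needed 20 reads in IP plus input. A window was called where the lower bound of the exact conditional binomial (Clopper-Pearson) 95% interval was above 1.5 and, for Ada2b, where the ratio was also more than 1.5 times that of the untagged IP over its input. Muscle and neurons were compared by the ratio of their IP/input ratios with a delta-method 95% interval, and a window was called higher in 1 cell type when the interval lay beyond 1.5-fold and the window was called there. These intervals compare libraries, not conditions, and PCR reads are not independent molecules. With 1 library per group no test across replicates was possible, and no p-value is given.

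The regions named in the text are, for each comparison and direction, the 5 with the highest lower bound after joining adjoining called windows, given by position, counted from 1, in dm3. Design steps on promoters, gene bodies, gene lists and the Pol II promoter to body ratio needed a dm3 gene annotation, which was not used here, so no gene is named and no exon or intron is assigned. The gene table at hand belongs to another assembly and was not applied to dm3 positions.

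After the data were seen, a restricted setting was added because X differed from the other arms in the pooled files and because those files held reads where no input had any. It scaled X and the other arms each to their own reads and kept the 113408 windows with at least 20 reads in each of the 3 inputs. Grouping by Pol II level and region width, the summit profiles and thinning of the muscle Ada2b library to 2597633 reads were also added then. Profiles used bins of 50 bases, reads moved 50 bases, and 1000 bootstrap draws of regions, and each summit was the highest point of Pol II over 250 bases. Log2 ratios for correlations had 1 added to both counts. Shared input was checked with 20 simulations of unchanged libraries and by splitting the muscle input at random. Set beforehand as other ways of counting were keeping all reads, scaling on the lower-count windows, a bound of 2, a wider interval, no read minimum, a shift from the estimated fragment length, other inputs, no untagged control, 500-base windows and IP against IP.

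The calling rule was tested, without its untagged step, on simulated reads with 200 changed windows per fold among the real ones. The changed windows had at least 20 input reads, and the simulation held counting noise only. False calls in real libraries can be more frequent, since the rule called 95 to 423 windows between inputs. For Ada2b in muscle (114201 windows) it recovered 33% of windows changed 2-fold and 100% of those changed 3-fold, with 5 false calls. For Ada2b in neurons (114014 windows) it recovered 31% and 95.5%, with 12 false calls, and for Pol II (114305 windows) 50.5% and 99%, with 3. For the untagged IP (114049 windows) it recovered 24.5% and 94%, with 12 false calls. For muscle raised over neurons (113549 windows) it recovered 12% at 2-fold, 65% at 3-fold and 93% at 4-fold, with 1 false call. Rises in neurons over muscle were not simulated. Over 5220 regions, simulated libraries without a difference between the sides of the summits gave a quotient of 1.00, and a simulated 1.2-fold difference came back as 1.2. The median window held 30 distinct reads for Ada2b in muscle, 21 for Ada2b in neurons, 24 for Pol II, 21 for the untagged IP and 86 to 90 for the inputs. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used.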

Results

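Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map Ada2b, a subunit of the SAGA transcriptional coactivator complex, and RNA polymerase II (Pol II) in Drosophila melanogaster embryos of stage 15 to 16. Embryos were dissociated, cross-linked, and sorted by flow cytometry for cells carrying GFP under a Mef2 muscle driver or an elav neuronal driver. Ada2b carried a FLAG tag and was expressed from a transgene under the same driver, per the genotypes in the labels. The 7 libraries were 1 Ada2b immunoprecipitate (IP) from muscle, 1 from neurons, 1 Pol II IP from muscle, 1 FLAG IP from neurons of a strain without the tag, and 1 input each from tagged muscle, tagged neurons and untagged neurons. Per the labels, the Ada2b and Pol II IP files each pooled 2 replicates. A pooled file is counted here as 1 library, since its replicates were not separated. Each group thus had 1 library, no value has a replicate error, and intervals cover counting error only unless stated. The files held 11973257 reads for Ada2b in muscle, 8986679 for Ada2b in neurons, 6723384 for Pol II and 2441082 for the untagged IP. The muscle, neuronal and untagged inputs held 10046153, 10548589 and 10047921 reads. After keeping 1 read per position and strand, 3922020, 2597923 and 5636532 reads were left for Ada2b in muscle, Ada2b in neurons and Pol II, and the other files were unchanged.

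The first comparison asked where Ada2b was bound in muscle. Ada2b was enriched over input in 2423 of 114440 tested windows of 1 kb (2.12%), with a median IP/input ratio of 2.48. Of these windows, 1155 lay on X, and 254 had fewer than 20 reads in at least 1 input. The 5 leading regions under the planned ranking had no muscle input read at their highest window. The first was 4 1286001 to 1293000, with 637 IP reads. With the input set to a floor of 3 reads it was 544-fold higher than the input, and the exact lower bound without the floor was 441. The others were X 21764001 to 21767000, 21784001 to 21789000, 21799001 to 21806000 and 21771001 to 21778000. They were 213-fold, 204-fold, 187-fold and 180-fold higher by the floor, with exact lower bounds of 172, 165, 151 and 145. With all reads kept, the 4 floor values on X were 69.6, 66.8, 61.3 and 59.0. After the data were seen, a restricted setting was added, in which X and the other arms were scaled apart and windows needed 20 reads in every input. In it, 1719 of 113408 windows (1.52%) were called, 260 of them on X, with a median ratio of 2.39. The leading windows were then 4 613001 to 614000, with 335 IP and 22 input reads and a ratio of 42.0 (95% interval 27.3 to 67.9), 2R 19963001 to 19964000 at 13.3 (11.1 to 15.9), 2R 16832001 to 16833000 with an interval of 10.9 to 15.5, 2L 8429001 to 8430000 at 15.3 (10.9 to 22.0) and 3R 25999001 to 26000000 at 9.83 (8.19 to 11.9). The untagged ratio at 2R 16832001 was 2.01 (1.44 to 2.77), and the next window, 2R 16833001 to 16834000, was itself among the 5 leading untagged windows of the restricted setting at 2.77 (2.05 to 3.72). At 4 613001 the 3 inputs held 22, 22 and 20 reads, and Pol II had a ratio of 25.8 and the untagged IP 0.824, so reads that align to several places were not ruled out there. Called windows were mostly isolated, since 1137 of the 1348 joined regions were a single window and 73 spanned at least 3 kb. With the neuronal or the untagged neuronal input in place of the muscle input, the planned rule called 3994 or 4535 windows.

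In neurons, fewer windows passed. Ada2b was called in 1499 of 114316 windows (1.31%), 882 of them on X, and in 786 of 113408 (0.693%) under the restricted setting, with a median ratio of 2.75. The muscle library was deeper, but thinning it to the number of neuronal reads left 1583 restricted windows in muscle. Under the planned ranking, 4 1286001 to 1293000, X 6001 to 15000, X 21764001 to 21767000, X 21784001 to 21787000 and X 21771001 to 21778000 led, without a neuronal input read at their highest window. They were 545-fold, 310-fold, 309-fold, 269-fold and 203-fold higher by the same floor, with exact lower bounds of 442, 250.04, 249, 217 and 163. With all reads kept, the 4 floor values on X were 89.6, 89.2, 77.9 and 58.7. In the restricted setting, the leading windows were 4 613001 to 614000, with 297 IP and 22 input reads and a ratio of 58.2 (37.7 to 94.2), X 21834001 to 21835000 at 21.8 (14.4 to 34.2), X 13685001 to 13686000 at 15.7 (10.8 to 23.5), 2L 8429001 to 8430000 at 14.4 (10.5 to 20.2) and 2R 2190001 to 2191000 at 10.6 (7.24 to 15.7). The last 4 of these rested on 26, 33, 51 and 40 neuronal input reads, against a median of 90 over all tested windows. All 5 were also high for Ada2b in muscle, at ratios from 6.51 to 42.0, and for Pol II, from 2.75 to 25.8. Reads that align to several places were thus not ruled out at these windows either. The untagged ratio at X 21834001 was 2.40 (1.33 to 4.22). Scaling on background windows gave 849 neuronal windows and keeping all reads gave 2841.

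Background was measured in the same way in cells without the tag. The FLAG IP from untagged neurons was called in 185 of 114106 windows (0.162%), and in 174 (0.153%) under the restricted setting. The leading windows under the planned rule were X 2690001 to 2691000 with a ratio of 3.93 (3.16 to 4.88), X 12818001 to 12819000 at 3.79 (2.33 to 6.16), 2R 6867001 to 6868000 at 4.12 (2.27 to 7.47), 2R 15415001 to 15416000 at 4.63 (2.23 to 9.71) and 4 389001 to 390000 at 3.63 (2.15 to 6.12). The Ada2b rule takes out windows with a high untagged ratio. Before that step, 10 of 1830 restricted Ada2b windows in muscle were also called in the untagged IP, against 2.81 for independent lists, and 19 of 886 in neurons, against 1.36. The step took out 111 and 100 windows. Across the 113408 restricted windows, which are not independent replicates, the log2 ratio of the untagged IP correlated with that of neuronal Ada2b at r = 0.23 (Spearman 0.22) and with that of muscle Ada2b at r = 0.03 (Spearman 0.02). Neuronal and muscle Ada2b correlated at r = 0.21 (Spearman 0.16), no higher than neuronal Ada2b and the untagged IP. When 1 input was set against another in place of an IP, the same rule called 95 to 423 windows over the 6 ordered pairs, and 64 to 328 under the restricted setting. The untagged control came from neurons, and no untagged muscle library was used here.

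Pol II was found over a larger part of the genome than Ada2b. It was called in 12728 of 114289 windows in muscle (11.1%), of which 7766 lay on X. Under the restricted setting it was called in 10022 of 113408 windows (8.84%), of which 1878 lay on X, with a median ratio of 2.82, and these formed 5278 regions with the longest spanning 62 kb. The planned ranking was led by 4 1286001 to 1293000, X 21799001 to 21806000, X 21764001 to 21767000, X 21784001 to 21786000 and X 21771001 to 21778000, with no muscle input read at the highest window. They were 199-fold, 165-fold, 162-fold, 130-fold and 118-fold higher by the floor, with exact lower bounds of 161, 133, 131, 104 and 94.8. With X scaled apart, the 4 floor values on X were 65.6, 64.4, 51.6 and 46.9. In the restricted setting the leading windows were 3R 2075001 to 2076000 with a ratio of 30.6 (24.2 to 39.1), 3R 2061001 to 2062000 at 26.7 (21.5 to 33.6), 2R 16832001 to 16833000 at 22.7 (19.3 to 26.9), 2R 19963001 to 19964000 at 22.5 (18.9 to 26.8) and 3R 25999001 to 26000000 at 21.9 (18.5 to 26.1). The last 3 of these windows were also among the 5 leading Ada2b windows in muscle. Scaling on background windows raised all Pol II ratios by 1.42 on the log2 scale and the count to 37979. Pol II was set against the input of the tagged muscle strain, since no input of its own strain was used here.

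The next comparison asked how far Ada2b and Pol II shared sites in muscle. Nearly all Ada2b windows in muscle also carried Pol II, while most Pol II windows carried no Ada2b call. A missing call does not mean that Ada2b was absent. Of the 8435 restricted Pol II windows without an Ada2b call, 7476 had an Ada2b ratio above 1 in muscle, with a median of 1.37. Of the 2423 Ada2b windows, 2134 (88.1%, Clopper-Pearson 95% interval 86.7 to 89.3) were called for Pol II, against 270 for independent lists of these sizes. Under the restricted setting, 1587 of 1719 (92.3%, 91.0 to 93.5) were shared, against 152 for independent lists, and they made up 15.8% of the Pol II windows. Ada2b in neurons overlapped muscle Pol II less, at 349 of 786 restricted windows (44.4%, 40.9 to 48.0), and no neuronal Pol II library was used here. The share of windows with Ada2b rose with Pol II in muscle, from 0.470% (0.380 to 0.573) at Pol II ratios of 1 to 2 to 4.97% (4.49 to 5.47) at 2 to 4, 50.4% (48.3 to 52.6) at 4 to 8 and 98.5% (94.6 to 99.8) at 8 to 16, and 17 of 17 windows (80.5 to 100%) at 16 or more were called. In neurons the shares in the same classes of muscle Pol II were 0.626%, 1.88%, 6.96%, 41.7% and 88.2%. For the untagged IP they were 0.0831%, 0.116%, 0.0473%, 3.03% (4 of 132 windows) and 5.88% (1 of 17), with median ratios between 0.942 and 1.18. The untagged share at Pol II ratios of 8 to 16 (interval 0.832 to 7.58%) was above the 0.153% of all restricted windows. At 16 or more its interval was 0.149 to 28.7%. The median Ada2b ratio in muscle rose more evenly than the share called, at 1.03, 1.35, 2.03, 3.97 and 6.89 in these classes. Both muscle IPs used the same input, which can add to the overlap. With the input split at random between the IPs, 89.8% of restricted windows were shared (85.9% under the planned rule). With all reads kept, 70.8% were shared. The covariance of the log2 ratios was 0.25 in the restricted windows against 0.03 over 20 simulations with no effect, with r = 0.49 across windows against a simulated 0.31.

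**Figure D1:**
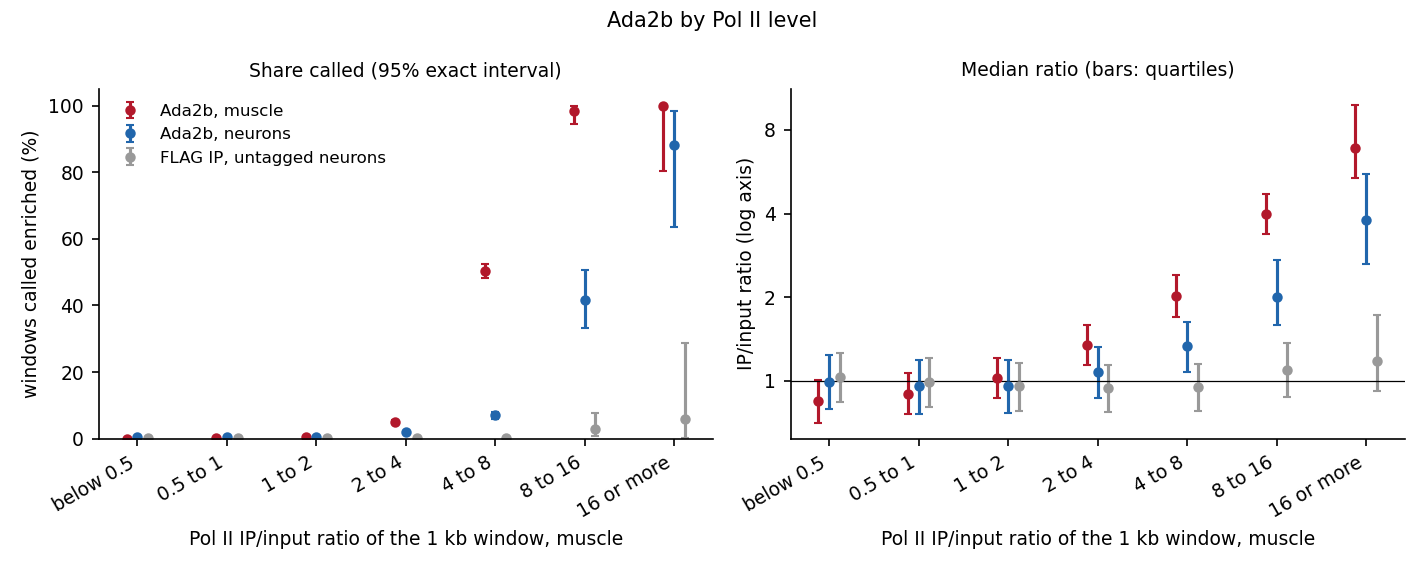
Ada2b and untagged FLAG IP signal in 1 kb windows grouped by the muscle Pol II IP/input ratio (x axis, restricted setting). Left, percent of windows called with 95% exact intervals; right, median IP/input ratio on a log axis with quartiles; the share called for Ada2b in muscle rises from 4.97% to 50.4% between the ratio classes 2 to 4 and 4 to 8.

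Ada2b followed Pol II in position as well as in level, by profiles chosen after the data were seen. Around 5220 Pol II summits of the restricted setting, each turned so that the side with more Pol II reads was on the right, the Ada2b ratio in muscle was 2.42 (bootstrap 95% interval over regions 2.39 to 2.46) over 250 bases at the summit. From 500 to 1500 bases on the side with more Pol II its interval was 1.18 to 1.21, and the ratio was 0.996 (0.986 to 1.01) on the other side. Pol II itself had ratios of 6.56, 1.92 and 1.13 at these places, the difference between the sides being set by the turning. Neuronal Ada2b had 1.41, 1.01 and 0.973, and the untagged IP 0.867, 0.953 and 0.990. The untagged IP came from neurons, so background of the FLAG IP at Pol II sites in muscle was not measured. Both muscle IPs also shared the same input. In the 344 regions of 5 kb or more, the ratio of Ada2b in muscle was 3.55 (3.38 to 3.72) at the summit, 1.80 (1.71 to 1.90) on the side with more Pol II and 1.27 (1.21 to 1.33) on the other. Wide regions were called for Ada2b at their summit window more often than narrow ones, at 56.2% (50.8 to 61.5) of 345 regions of 5 kb or more against 11.9% (10.9 to 13.1) of 3356 regions of 1 kb. Wide regions also had more Pol II. Among summits with a Pol II ratio of 4 to 8, the shares were 68.1% (61.3 to 74.4) of 207 and 41.6% (37.7 to 45.6) of 608, with median Pol II ratios of 5.74 and 4.77.

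**Figure D2:**
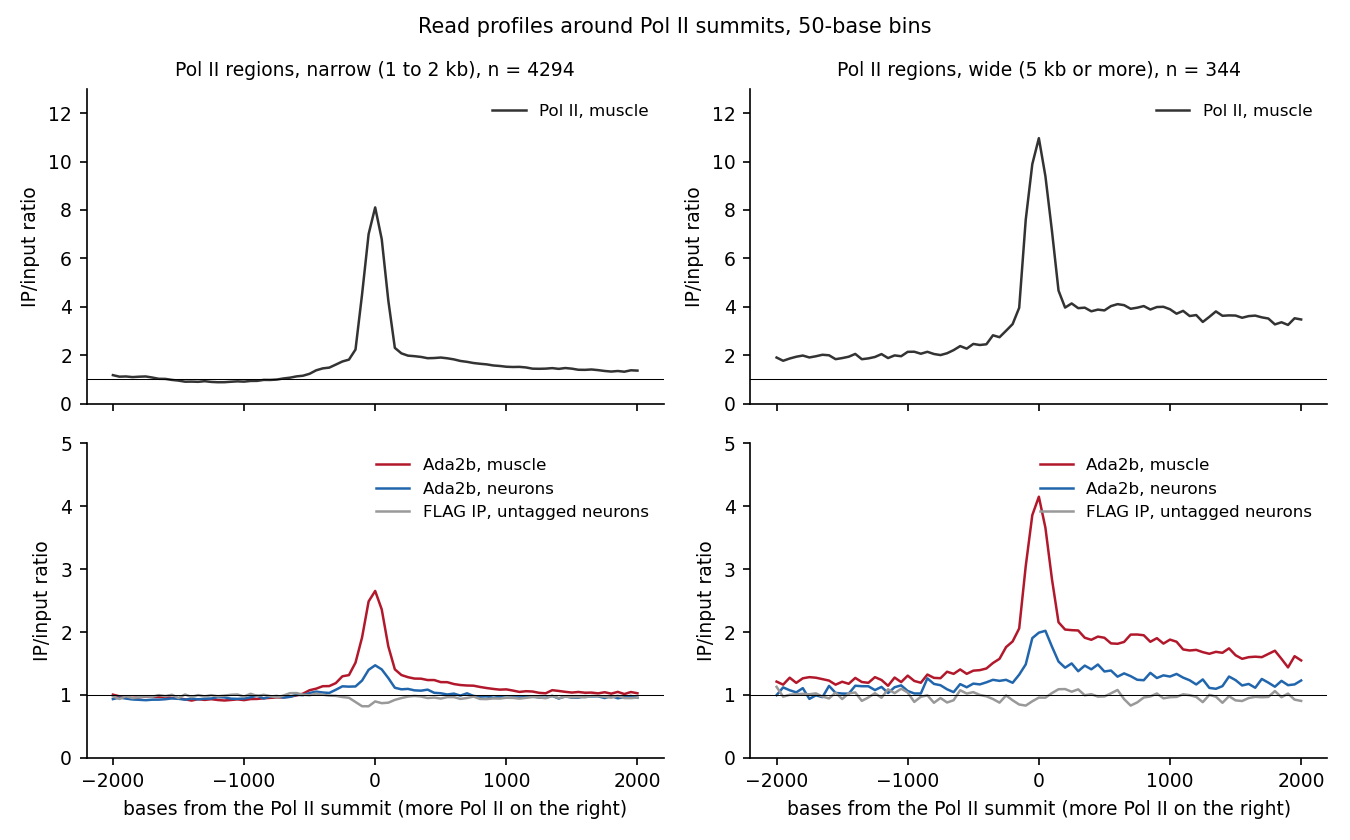
Summed IP/input ratios (y axes) in 50-base bins against the distance in bases from the Pol II summit (x axis), for 4294 narrow and 344 wide Pol II regions, with Pol II in the upper and Ada2b and the untagged FLAG IP in the lower panels. In wide regions Ada2b in muscle is above 1 on both sides, at 1.80 on the side with more Pol II and 1.27 on the other. The untagged IP, which came from neurons, is at 0.959 and 0.985.

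The main contrast of the study was Ada2b in muscle against neurons. Muscle had more windows with higher Ada2b under the planned rule, but not with all reads kept. Nearly all of the restricted windows higher in muscle carried Pol II in muscle, as did most muscle Ada2b windows. By the ratio of the IP/input ratios, 279 windows were higher in muscle and 147 in neurons under the planned rule, and 260 and 125 under the restricted setting. Of the 260 muscle windows, 257 (98.8%) had a Pol II call in muscle, against 92.3% of all restricted muscle Ada2b windows, from which they were drawn. Their median ratios were 5.92 for Pol II, 2.63 for Ada2b in muscle, 0.966 for Ada2b in neurons and 0.918 for the untagged IP. The same muscle input served the Ada2b and the Pol II ratio, so choosing windows by the Ada2b ratio can move both the same way. Of the 125 neuronal windows, 2 (1.6%) had a Pol II call in muscle, against 8.84% of all tested windows and 44.4% of all restricted neuronal Ada2b windows. The median ratios of the 125 were 2.87 for Ada2b in neurons, 0.824 for Ada2b in muscle and 1.248 for the untagged IP. Their median neuronal input was 41 reads, against 90 over all tested windows. The untagged and muscle inputs were low there too, at 51 and 68 reads against 87 and 86. In the restricted setting, 293 windows were called in both cell types, against 11.9 for independent lists, among them 11 of the 260 and 1 of the 125, with a median muscle to neuron log2 ratio of 0.15. Scaling on background windows gave 763 higher in muscle and 34 in neurons, and setting IP against IP without inputs gave 440 and 24. Keeping all reads gave 668 and 673, and centring on windows called in both cell types gave 225 and 177, so the excess in muscle depended on scaling and on repeated reads. With all reads kept, repeats count as independent reads, which makes the intervals too narrow. With inputs alone, the muscle input was called above the neuronal input in 223 restricted windows, which raises the ratio for neurons over muscle, and the neuronal above the muscle input in 114. The count for neurons was below the 223, and the count for muscle was above the 114. These counts cannot be compared directly, since the inputs were deeper than the IPs and were set against each other by a single ratio.

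Under the planned rule, the windows leading in muscle were 2R 1165001 to 1166000, which had 3 muscle input reads and 48 in the neuronal input (log2 ratio 3.77, 1.91 to 5.62), X 13198001 to 13199000 (2.62, 1.59 to 3.64), 2R 4488001 to 4489000 (2.27, 1.57 to 2.97), 2L 16787001 to 16788000 (2.13, 1.49 to 2.77) and X 1921001 to 1922000 (2.33, 1.47 to 3.20). The restricted ranking kept 2R 4488001 and 2L 16787001, and added 2R 20199001 to 20200000 (2.16, 1.48 to 2.83), 3R 4063001 to 4064000 (1.88, 1.41 to 2.35) and 2L 1163001 to 1164000 (2.10, 1.40 to 2.81). The longest of these regions, 2L 16782001 to 16788000, had an Ada2b ratio of 4.77 in muscle and 1.08 in neurons and a Pol II ratio of 13.7 in muscle at its leading window. The windows leading in neurons were 2R 2160001 to 2161000 (log2 muscle to neuron ratio -3.68, -5.55 to -1.82), X 3936001 to 3937000 (-2.95, -4.09 to -1.81), 2R 15410001 to 15411000 (-2.71, -3.76 to -1.66), 3L 12877001 to 12878000 (-2.71, -3.77 to -1.66) and 2L 22885001 to 22886000 (-2.83, -4.07 to -1.59). These 5 rested on 18, 31, 37, 36 and 25 neuronal IP reads against 8, 41, 51, 41 and 39 neuronal input reads. The restricted ranking left out 2R 2160001 and X 3936001 and added X 15021001 to 15022000 (-2.67, -3.68 to -1.65) and 3L 23969001 to 23970000 (-2.91, -4.27 to -1.55). The calls at X 13198001 and X 3936001 were lost with all reads kept, with the lower bound above 2, with a wider interval and with X scaled apart. The call at 2L 22885001 was lost with background scaling, the bound of 2 and the wider interval, and that at 2R 15410001 with the last 2 of these. The call at 2R 2160001 was lost with the wider interval, and that at X 1921001 with all reads kept. Apart from 2R 2160001, these calls ended because the window was no longer called over input in the higher cell type. With X scaled apart the log2 ratio was 2.54 (1.51 to 3.57) at X 13198001 and -3.03 (-4.17 to -1.89) at X 3936001. With all reads kept it was 2.42 (1.49 to 3.35), -3.21 (-4.32 to -2.10) and, at X 1921001, 1.90 (1.13 to 2.66), and with background scaling -2.54 (-3.78 to -1.29) at 2L 22885001. At 2R 2160001 the wider interval was -6.82 to -0.55. The untagged call at 2R 15415001 was also lost with the wider interval.

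**Figure D3:**
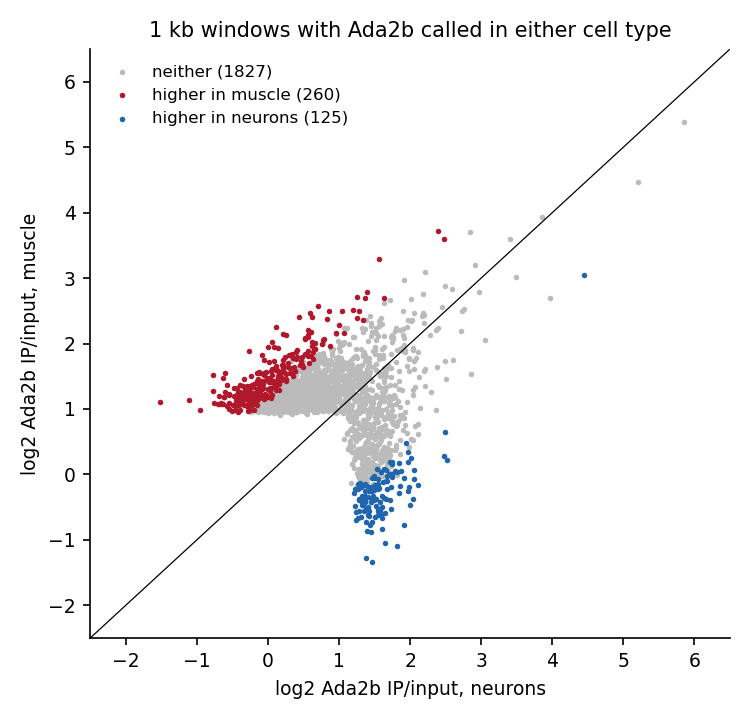
Log2 IP/input ratio of Ada2b in muscle (y axis) against neurons (x axis) for 1 kb windows called in either cell type under the restricted setting, 1 point per window. The 260 windows higher in muscle and the 125 higher in neurons are coloured, and the empty centre below a log2 ratio of about 1 in both follows from plotting called windows.

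**Figure D4:**
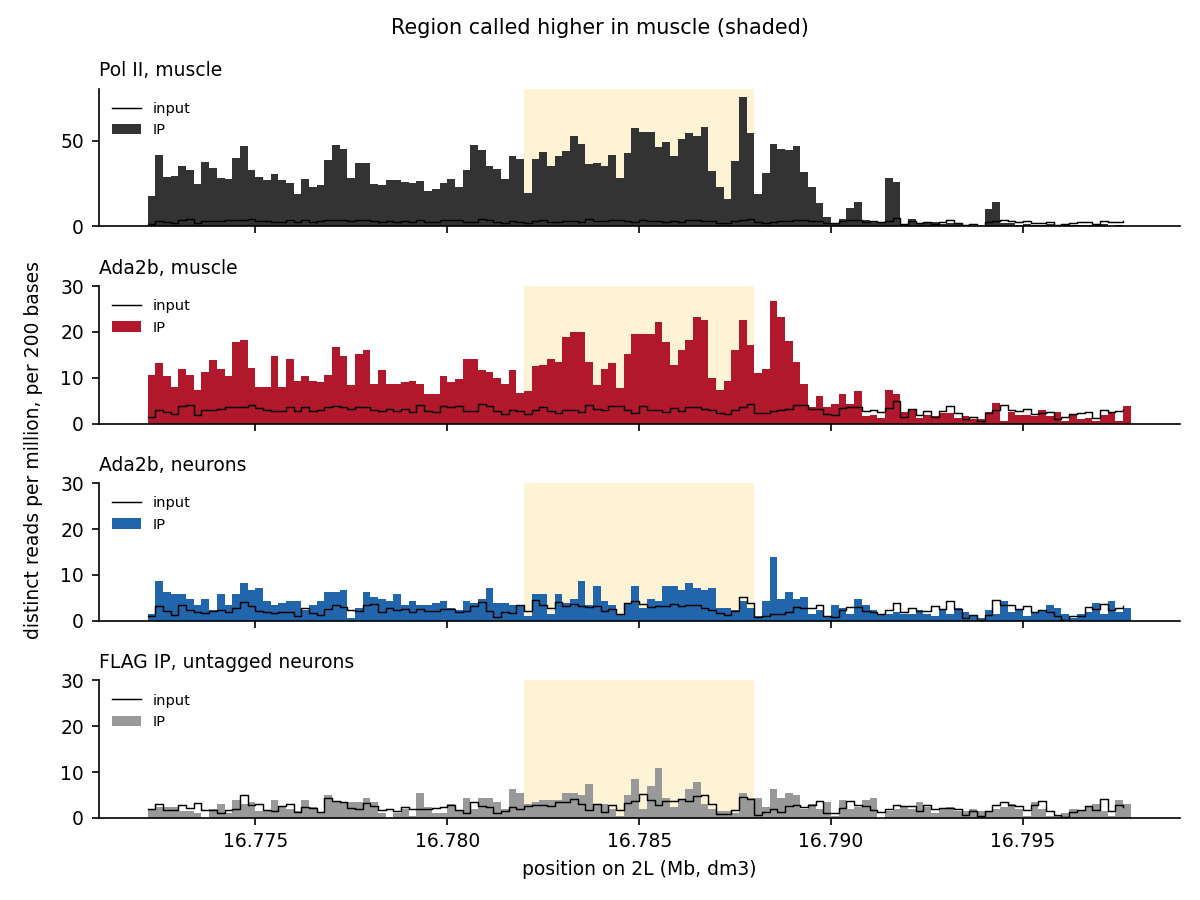
Distinct reads scaled to those on the arms other than X (RPM) in 200-base bins (y axes) from 16772201 to 16797800 on 2L (x axis, dm3), as bars for each IP and a line for its input. The shaded region, 16782001 to 16788000, was called higher in muscle. The highest bin shown reached 75.5 for Pol II and 10.8 for the untagged IP, both inside the shaded region. For Ada2b the highest bin lay outside the shaded region, at 26.7 in muscle and 13.9 in neurons. Inside the shaded region, Ada2b reached 23.2 in muscle and 8.62 in neurons.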

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

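The tests in this part were chosen after the result was seen, except the test of the windows higher in neurons against the other neuronal input.

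On arms other than X, 72.2% of the rows for Ada2b in muscle, 74.8% for Ada2b in neurons and 23.4% for Pol II repeated an earlier position and strand, against none in the untagged IP and the inputs, and these rows were outside the main counts. X held 6.80%, 7.93% and 31.0% of the rows in these files, against 14.7% to 16.8% in the inputs. Stronger binding on X alone is argued against by the windows with little signal, since the 10th percentile of the Pol II ratio was 4.33 times as high on X as elsewhere, more than the 90th percentile at 3.36 times. For Ada2b the 10th and 90th percentiles rose about alike on X, 1.55 and 1.50 times in muscle and 1.39 and 1.42 times in neurons. Removal of repeated reads on X alone leaves distinct reads as they are, yet X had 1.41, 1.33 and 2.51 times its input share of distinct reads in the 3 files, against 1.00 in the untagged IP. A different set of reads may have been used for X. The value of 4.33 met the test set for this, but that test cannot single it out. It rests on the same Pol II value as the test of binding, and any even rise on X would meet it. Which step produced the rise, and why X had few or no repeats, stays open.

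The pooled IP files also held reads in places with none in any input, and windows without a read in the matching input led their planned rankings. Over 4318 windows without an input read, Ada2b in muscle had 6762 reads, Ada2b in neurons 5048, Pol II 5044 and the untagged IP 21. At equal depth the untagged reads were 0.443% of those of neuronal Ada2b, so reads that align to several places may have been kept in the pooled files and left out of the others. Binding alone leaves the inputs unexplained, because in the windows with no muscle input read and at least 20 muscle Ada2b reads the other inputs had 0.318% of their usual count. Binding at these places on top of that was not tested.

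Under the planned rule, 11 windows were called higher in muscle with a neuronal ratio below 1 by its whole interval, and 8 were called higher in neurons with a muscle ratio below 1 in the same way, a difference between cell types that was not tested across replicates. Among the 125 restricted windows higher in neurons, 22 (17.6%) were still called with the untagged neuronal input, which called 118 in all. Chance low counts in the neuronal input may thus account for part of this class. The untagged and muscle inputs were also low in these windows, at medians of 51 and 68 reads against 87 and 86 over all tested windows. Chance losses in a single input were therefore not told apart from windows of low coverage in every input. Of the 260 higher in muscle, 208 were still called with the untagged neuronal input in place of the muscle one. That input comes from another cell type and called 1112 in all. Background of the FLAG IP in neurons cannot be told apart from binding there, as the median untagged ratio of 1.248 lay between the values set for either outcome. It lay just below the upper of these values. The untagged step had also already taken out windows with a high untagged ratio, which lowers this median. In the windows higher in muscle the untagged ratio was 0.918. A difference between the cell types stays open and untested.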

How the results depend on the processing

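The settings on X and on depth were chosen after the result was seen; the others were planned. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible. No named window changed direction. Of the 30 entries named by the planned rule, between 24 and 30 kept their call under each setting that could test all of them. Several windows were entered for more than 1 IP. Those without a matching input read had lower bounds far above the thresholds, so these settings could hardly end their calls. The restricted setting could test 12 of the 30 entries, of which 10 kept their call. Keeping all reads gave 2841 Ada2b windows in neurons and 70.8% of muscle Ada2b windows with Pol II. It gave 668 higher in muscle and 673 higher in neurons, so no excess in muscle was seen. The count in muscle became 3257, within 1.5 times the planned one, yet 1320 of the 2423 planned windows were among them. In neurons, 660 of the 1499 planned windows were still called. With all reads kept, repeated rows count as independent reads. The Ada2b files had 3.59 (muscle) and 3.96 (neurons) rows per position on the arms other than X, against 1.0 in the inputs. The intervals are then too narrow, so this setting cannot decide whether muscle had an excess. Scaling on background windows, which raised all muscle to neuron ratios by 0.29 on the log2 scale, gave 849 in neurons, 37979 for Pol II, 89 for the untagged IP, 763 higher in muscle, 34 higher in neurons and 95.3% shared. A lower bound above 2 gave 911 in muscle, 510 in neurons, 8431 for Pol II, 10 for the untagged IP, 31 and 21 higher in muscle and neurons and 85.7% shared. A wider interval gave 1255, 484 and 10 windows for Ada2b in muscle, in neurons and the untagged IP, and 38 and 4 higher in muscle and neurons. IP against IP gave 440 and 24. The share with Pol II was 85.2% with 500-base windows, 89.97% within 1 window and 85.9% with the input split. With X scaled apart and 20 reads in each input, neurons had 786 windows and the share was 92.3%. Without X, neurons had 823 windows and Pol II 8243, of which 617 and 4962 were among the planned calls, since the other arms were also rescaled. With other inputs, muscle had 3994 (neuronal) and 4535 (untagged), neurons 801 (muscle), and the untagged IP 305 (muscle) and 518 (neuronal). Unless stated, the cause was not tested. No read minimum, the estimated shift, leaving out the untagged control, centring, X scaled apart alone and thinning to neuronal depth kept each count they were run on within 1.5 times. A similar count need not hold the same windows. X scaled apart alone kept 1601 of 2423 planned Ada2b windows in muscle, 858 of 1499 in neurons and 6907 of 12728 for Pol II. Gene-level alternatives were not run, for want of an annotation in dm3. At this depth, 12% of simulated 2-fold rises in muscle over neurons were recovered, and rises in neurons were not simulated.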

Other observations

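The values and tests in this part were chosen after the data were seen. Chromosome 4 had the highest share of called windows of any arm in each of the 4 IPs under the restricted setting. Ada2b was called in 3.47% of its 1153 windows in muscle and 4.60% in neurons, against at most 1.82% and 0.744% on the other arms. Pol II was called in 16.9% there and in 7.33% to 10.5% elsewhere, and the untagged IP in 0.781% against 0.106% to 0.231%. Of the 71 windows with no muscle input read and at least 20 muscle Ada2b reads, 21 lay on 4. The restricted setting leaves those windows out, but reads that align to several places were not ruled out in the others on 4. Input reads on 4 were 1.30 times as frequent in muscle as in tagged neurons and 1.33 times as frequent as in untagged neurons, as medians over 13 bins of 100 kb.

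A small set of Ada2b windows in muscle carried no Pol II call. These 132 restricted windows had a median Ada2b ratio of 2.50, a median Pol II ratio of 1.42 and an untagged ratio of 1.00, and 48 of them were also called in neurons. Among the 1587 windows with Pol II, 245 were called in neurons, and the median Ada2b ratio was 2.38. The 8435 Pol II windows without an Ada2b call had a median Ada2b ratio of 1.37 in muscle, and 7476 of them had a ratio above 1, against 44422 of all 113408 tested windows.

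The window X 2690001 to 2691000 was high in all 4 IPs, with restricted ratios of 4.43 for Ada2b in muscle, 3.62 for Ada2b in neurons, 2.98 for Pol II and 3.92 for the untagged IP. Its muscle, neuronal and untagged inputs were 5.19, 3.41 and 2.27 times the median of X. Close by, X 2684001 to 2687000 had inputs at 4.67, 4.20 and 3.86 times that median. The highest such run in muscle was X 8188001 to 8190000, at 11.3, 7.35 and 5.92 times.

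The inputs differed between strains in places. In bins of 100 kb, 2R 10900001 to 11000000 stood at 0.502 times the median of its arm in the tagged neuronal input, against 0.836 in muscle and 0.833 in untagged neurons. On 2L, 22500001 to 22600000 stood at 0.740 in tagged neurons, 0.495 in muscle and 0.525 in untagged neurons. The tagged neuronal strain carried a CyO balancer, per the genotype in the labels, and its effect was not tested. Relative to untagged neurons, X had 0.863 times the input reads in tagged neurons and 0.877 times in muscle. The estimated fragment length on X minus that on the other arms was -7, -11 and 15 bases in the Ada2b muscle, Ada2b neuronal and Pol II files, and from -2 to 2 bases in the untagged IP and the inputs.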
